A study of Mus musculus with 12 samples.

How the data were processed

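RNA sequencing was available for the gastrocnemius, a calf muscle, and the hypothalamus of 6 male BALB/c mice. Per the labels, 3 mice had received CT-26 cells, a mouse colon carcinoma line, under the skin of the abdomen and had developed cachexia, the wasting of body tissue that accompanies some tumours, and 3 were controls. This gave 12 libraries in 4 groups of 3, each library from a separate tissue of a numbered mouse, so replicates within a group were separate mice. Per the labels' protocols, the libraries were made with a directional MGIEasy RNA kit and read as 100 bp pairs on an MGISEQ-2000.

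Per the submitters' processing notes, the authors used Trim Galore 0.6.6, STAR 2.7.9a and RSEM 1.3.3 with the mouse build GRCm38. The deposited gene tables hold RSEM expected counts, which are estimated numbers of fragments per gene that need not be whole because reads matching several transcripts are divided by probability. The deposited tables also hold TPM and FPKM values and an effective length per gene, and the deposited TPM values were used for 1 alternative here; FPKM was not used. The annotation release and the strand setting of the counting were not given in the sources used here. Of the 55416 gene identifiers, 52135 were named from the GENCODE M21 annotation of GRCm38, and the 3281 identifiers without a name there were kept under their identifiers; named genes held 99.648% of counts. Coordinates are those of that annotation on GRCm38, 1-based, and cover the whole gene from first to last exon.

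Expected counts were rounded to whole numbers before testing. The library totals ran from 26015741 to 52535761, and CPM below means counts scaled to a common library total, in parts per 1e6, after scaling by TMM, edgeR's trimmed mean of M-values. No 2 libraries of a group agreed within sampling noise: chi-square per gene between replicates ran from 6.38 to 182.4, so each counted as 1 replicate. Each tissue was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, with the filterByExpr minimum, TMM factors, the quasi-likelihood test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment; a gene was called at an adjusted p below 0.05. This left 14265 genes in the gastrocnemius and 17961 in the hypothalamus. The difference between tissues was the interaction term of a fit of all 12 libraries over 18746 genes, and an effect was described as differing between tissues for genes among the 13572 tested in both tissues. Standard errors are those of log2 fold changes, taken from the test statistic. Overlap of calls was tested with a two-sided Fisher's exact test.

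Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. The rule took, per tissue, the 4 genes with the highest and the 4 with the lowest log2 fold change among called genes with a mean log2 CPM of at least 1 and no overlap between the groups, leaving out predicted models, immunoglobulin and T-cell receptor segments and pseudogenes. It added up to 3 called members with the smallest p from each list that passed the set test and up to 1 from each other list, and 8 genes per tissue whatever they showed: Trim63, Fbxo32, Mstn, Foxo1, Socs3, Cebpd, Pdk4 and Myh4 in the gastrocnemius, and Npy, Agrp, Pomc, Cartpt, Crh, Trh, Lcn2 and Socs3 in the hypothalamus. For the difference between tissues it took the 4 largest interaction coefficients in each direction among called genes tested in both tissues, with the same kinds of genes left out. It added the fixed genes tested in both tissues. Some genes that the rule took are not reported here. Other members of the fixed lists are given as examples, chosen after their values were seen. Lists with at least 5 measured members were tested against all other genes with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 30 lists in the gastrocnemius and 27 in the hypothalamus. Camera with a correlation estimated from the libraries and fry were run beside it; no list passed an adjusted p of 0.05 with an estimated correlation, and that value stands beside every list called. Camera asks for a shift in 1 direction, so a list that was not called may still hold members that changed both ways. Results of fry are given with the alternatives. Its mixed test, for change in either direction without comparison to other genes, is given for the clock lists only. In the phrase "adjusted over the list alone", only the members of a list were adjusted together.

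The fits were tested on simulated counts with 200 changed genes. In the gastrocnemius simulation, over 14045 genes, 5.97% of 1.5-fold, 52.3% of 2-fold and 95.5% of 4-fold changes were recovered; in the hypothalamus simulation, over 17740 genes, these were 71.4%, 91.0% and 100%; in the interaction simulation, over 18516 genes, they were 2.99%, 34.3% and 71.2%. Of the calls made there, 11.4%, 12.3% and 5.26% were genes simulated without change, so in both single-tissue simulations the share of false calls lay above the 5% aimed for. The draws were not repeated. The 200 changed genes were far fewer than the genes called in the data, so these shares need not carry over to the real fits. CPM of low genes carry counting error, PCR duplicates are not independent molecules, and intervals from counts cover counting error only.

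The titles number the mice, and the gastrocnemius and hypothalamus with the same number and treatment were read as from the same mouse; a fit with the mouse as a block was an alternative for the interaction. The expression deviations of same-numbered tissues correlated between -0.103 and 0.167, so these correlations alone do not show this pairing. CT-26 and control mice share only a number. The other alternatives were DESeq2 1.42.0, its median-of-ratios (RLE) factors in edgeR, library totals without TMM, no minimum count, a minimum of 1 CPM in 3 libraries, offsets from the effective lengths, limma 3.58.1 on log2(TPM + 0.5), an adjusted p below 0.01, 1 fit of all 12 libraries, and leaving out each mouse or library in turn. Library totals and TPM shifted the median log2 change of all gastrocnemius genes from 0.00 to 0.20 and 0.28, so gastrocnemius changes are relative to the TMM scale.

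Some counts are shared or uncertain. Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Amd1 and Amd2, and Hspa1a and Hspa1b are near-identical pairs among which RSEM divides reads. With the strand setting unknown, reads of overlapping genes cannot be told apart with certainty; this concerns Agrp (overlapping Ctcf and Ripor1), Alas2, Cdh15, Chad, Fbxo31, Fdft1, Gadd45a, Gpr17, Icam1, Irf9, Ndufs1, Paox and neighbouring mitochondrial genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.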

Results

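The series compared mice bearing CT-26 colon carcinoma with control mice, in a calf muscle that wastes in cachexia and in the brain region that controls appetite and energy balance. Per the labels, the CT-26 mice weighed 7 to 10% less by day 10 and their tissues were collected on day 25. The labels give an age of 7 weeks for all mice, and a collection day for the CT-26 mice only. Whether control tissues were collected at the same time is therefore not known here. There were 4 groups of 3 libraries: CT-26 gastrocnemius, control gastrocnemius, CT-26 hypothalamus and control hypothalamus. Library totals ran from 26015741 to 42771331 expected counts in the gastrocnemius and from 27195316 to 52535761 in the hypothalamus. In the gastrocnemius 70.1% of the variance of log2 CPM lay on a first principal component that separated the CT-26 from the control libraries, and in the hypothalamus 46.4% did. Values below are TMM-normalised CPM as mean ± SD over 3 mice, and log2 fold changes are CT-26 over control. P-values of genes are from edgeR's quasi-likelihood test and those of lists from camera, with Benjamini-Hochberg adjustment. Listed genes outside the naming rule fixed before the data were examined were chosen after their values were seen: in the gastrocnemius Trim32, Atg12, Phgdh, Chrne, Ifitm3, Lyz2, Pdgfra, Lox and Col1a1. In the hypothalamus these were Hcrt, Pmch, Gal, Glp1r, Lepr, Ghrh, Saa3, Ifit3, Ifitm3, Mal, Mobp, Pdgfra, Cspg4, Fos, C1qa, C1qb, Pitx1 and Slc6a3.

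In the CT-26 gastrocnemius, transcripts of the protein breakdown machinery were higher. Trim63 and Fbxo32, which encode the muscle ubiquitin ligases MuRF1 and atrogin-1, rose 10.6-fold and 11.6-fold, from 105.7 ± 10.3 to 1126 ± 256 CPM (SD, n = 3) and from 163.4 ± 40.3 to 1902 ± 271 CPM (SD, n = 3). Among listed genes, 28 of 31 proteasome subunits, 13 of 22 autophagy and lysosome genes and 11 of 15 glucocorticoid-responsive genes rose, while 17 of 22 extracellular matrix genes, 11 of 13 mitochondrially encoded transcripts and 6 of 15 fast sarcomere genes fell. None of these 6 lists passed with a correlation between genes estimated from the libraries (adjusted p = 0.06227, 0.1143, 0.1508, 0.2115, 0.4506 and 0.4506 with an estimated correlation). Of 14265 genes tested, 5417 were called, 2801 higher and 2616 lower, and 1028 and 1293 of them changed at least 2-fold. The 3 CT-26 libraries did not overlap the 3 control libraries for 51.7% of genes, against 10% by chance. The share of calls that were higher was 51.7% with TMM, 70.4% with library totals only and 81.5% with TPM. Without control mouse 1, 1768 genes were called higher and 1779 lower.

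Of the 13 listed ubiquitin ligases of muscle atrophy, 5 rose and 1 fell (camera adjusted p = 0.0006845; adjusted p = 0.2078 with an estimated correlation). Besides Trim63 (log2 3.41 ± 0.22 SE, adjusted p = 9.373e-05) and Fbxo32 (log2 3.54 ± 0.24 SE, adjusted p = 0.0001096), Fbxo31 rose by 1.67 on the log2 scale, and Trim32 fell by 0.70. Of 31 proteasome subunits, 28 rose and none fell (adjusted p = 7.48e-16; adjusted p = 0.06227 with an estimated correlation), among them Psmd4 (log2 1.85), Psma7 (1.65) and Psmd2 (1.40). Of 22 autophagy and lysosome genes, 13 rose and Atg12 fell (adjusted p = 3.272e-06; adjusted p = 0.1143 with an estimated correlation). Bnip3 and Bnip3l, receptors that mark mitochondria for removal, rose 3.36-fold and 2.36-fold, and the lysosomal protease Ctsl rose 3.85-fold. The counts for these 3 lists were the same when adjusted over the list alone.

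Several hormone and cytokine response genes rose in the same muscle. Of 15 glucocorticoid-responsive genes, 11 rose (adjusted p = 7.52e-10; adjusted p = 0.1508 with an estimated correlation). The transcription factor Cebpd rose 22.8-fold (11.3 ± 1.53 to 256.4 ± 65.9 CPM; SD, n = 3), the cell cycle inhibitor Cdkn1a 9.38-fold and the glucocorticoid receptor co-chaperone Fkbp5 7.60-fold. The metallothioneins Mt1 and Mt2, which bind zinc and other metals, rose 56.8-fold and 82.3-fold (log2 5.83 and 6.36, or 5.16 and 5.65 without CT-26 mouse 3). Pdk4, which restrains pyruvate oxidation, rose 2.46-fold. Of 17 IL-6/STAT3 and acute phase genes, 11 rose (adjusted p = 9.307e-09; adjusted p = 0.1143 with an estimated correlation), or 13 when adjusted over the list alone. The interleukin 6 receptor Il6ra rose 10.6-fold, the acute phase protease inhibitor Serpina3n 12.8-fold, the oncostatin M receptor Osmr 2.79-fold and the feedback inhibitor Socs3 6.45-fold (log2 2.69 ± 0.34 SE, adjusted p = 0.0008716). Of 13 NF-kB targets, 10 rose, the same count as adjusted over the list alone (adjusted p = 0.0004592; adjusted p = 0.2675 with an estimated correlation). The adhesion molecule gene Selp was at log2 3.06, the cytokine gene Il1b at 4.42 and Nfkbiz at 1.49. In the same libraries all 8 measured neutrophil genes rose, and some of the genes above, such as Il1b, are also expressed in neutrophils. Of 22 interferon response genes, Ifitm3 rose and 1 fell (adjusted over the list alone, 0 and 1), and the list was not called (adjusted p = 0.5184).

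Stress and signalling lists moved less uniformly. Among 15 genes of the amino acid and ATF4 stress response, 6 rose and 1 fell, or 6 and 2 when adjusted over the list alone (adjusted p = 0.01271; adjusted p = 0.4506 with an estimated correlation). Eif4ebp1, which encodes a repressor of cap-dependent translation, rose 10.3-fold. The glutathione-degrading enzyme gene Chac1 rose 4.49-fold and the amino acid transporter subunit gene Slc3a2 1.76-fold, while Phgdh of serine synthesis fell by 1.71 on the log2 scale. Of 14 endoplasmic reticulum chaperone genes 7 rose, the same count as adjusted over the list alone (adjusted p = 0.01271; adjusted p = 0.5734 with an estimated correlation). Xbp1 was at log2 1.31, Dnajb9 at 0.83 and Dnajc3 at 0.61. This list call was lost without CT-26 mouse 3 (adjusted p = 0.05635) and that of Dnajc3 without control mouse 1 (adjusted p = 0.05139). Among 21 growth factor and myostatin signalling genes, 6 rose and 5 fell, as also adjusted over the list alone, and the list was not called (adjusted p = 0.7048). Akt1, a kinase of insulin signalling, rose 4.83-fold and Foxo1, a transcription factor that drives atrophy genes, rose 3.43-fold (log2 1.78 ± 0.27 SE, adjusted p = 0.001822). Mstn, which encodes myostatin, was at 74.7 ± 5.35 CPM in CT-26 and 89.1 ± 31.0 CPM in control muscle (SD, n = 3) and did not pass the test (log2 -0.25 ± 0.23 SE, adjusted p = 0.4123). Of 19 circadian clock genes, 5 rose and 5 fell, or 7 and 7 when adjusted over the list alone. The clock list was not called (adjusted p = 0.6848), and its median (log2 -0.07) had the opposite sign to its test. Fry's mixed test, which asks for change in either direction, gave an adjusted p of 0.0005126.

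**Figure D1:**
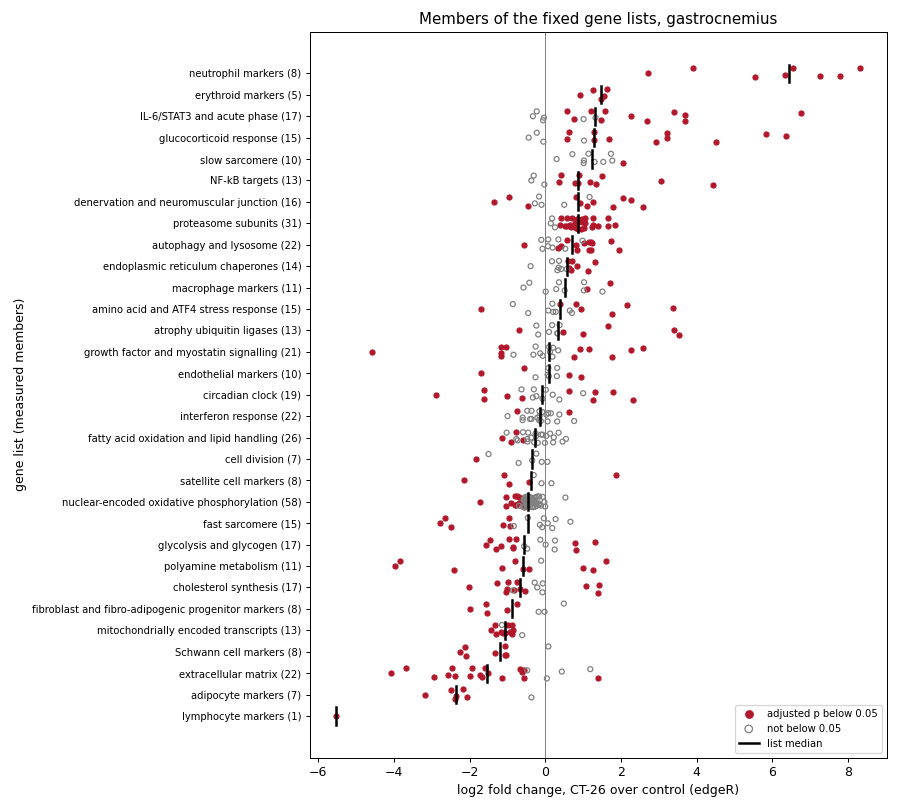
Log2 fold change (CT-26 over control) of each measured member of the fixed gene lists in the gastrocnemius, 1 line per list with its number of measured members; filled points have an adjusted p below 0.05, open points do not, and black bars are list medians. The median of the 8 neutrophil genes (6.44) lies farthest to the right, the 31 proteasome subunits lie right of 0 (median 0.86) and the 22 extracellular matrix genes lie mostly left of it (median -1.55).

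Genes of contraction and energy metabolism were in part lower. Of 15 fast sarcomere genes, 6 fell and none rose, as also adjusted over the list alone (adjusted p = 0.008619; adjusted p = 0.4506 with an estimated correlation). These 6 included the calcium-binding genes Pvalb (log2 -2.78; -3.54 without CT-26 mouse 2) and Casq1 (-2.50) and the light chain gene Myl1, which fell from 11962 ± 2245 to 1916 ± 892 CPM (SD, n = 3). The median of the fast list was -0.46 with TMM, -0.29 with library totals and -0.11 with TPM. Its call held with each, but camera compares a list with all other genes. The median of all genes was 0.20 with library totals and 0.28 with TPM. A call there shows a lower change than that of other genes, which need not be a fall. The gene of the fastest myosin heavy chain, Myh4, did not pass the test (log2 -0.83 ± 0.46 SE, adjusted p = 0.1884). Its per-mouse values were 20860, 49990 and 14050 CPM with CT-26 and 47910, 61870 and 41120 CPM in controls, and without CT-26 mouse 2 it was called (log2 -1.53, adjusted p = 0.005662). Of 10 slow sarcomere genes only Myoz2 rose (log2 2.06), also when adjusted over the list alone. The slow list was not called (adjusted p = 0.07376), but it was without CT-26 mouse 2 (adjusted p = 0.0001478) or control mouse 3 (adjusted p = 0.01248). Of 16 denervation and neuromuscular junction genes, 8 rose and 3 fell, as also adjusted over the list alone (adjusted p = 0.04404; adjusted p = 0.4506 with an estimated correlation). The stress gene Gadd45a rose 3.44-fold, the transcription factor gene Runx1 4.14-fold and the acetylcholine receptor subunit gene Chrnb1 2.17-fold, while the adult receptor subunit gene Chrne fell by 1.36 on the log2 scale. The denervation call was lost with TPM and with a minimum of 1 CPM in 3 libraries, and also without CT-26 mouse 1 (adjusted p = 0.08318) or control mouse 1 (adjusted p = 0.0825).

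All 13 mitochondrially encoded transcripts were below control and 11 of them fell, or 12 when adjusted over the list alone (adjusted p = 0.0002335; adjusted p = 0.4506 with an estimated correlation). They included mt-Co2 (log2 -1.44), mt-Nd4l (-1.31) and mt-Nd5 (-0.99). The call of mt-Nd5 was lost without CT-26 mouse 1 (adjusted p = 0.05393) or 3 (adjusted p = 0.05114). Mitochondrial transcripts made up 8.26, 10.1 and 11.1% of counts in the CT-26 libraries and 15.2, 13.5 and 19.7% in the controls. Of 58 nuclear-encoded oxidative phosphorylation genes, 14 fell and none rose, or 11 when adjusted over the list alone (adjusted p = 0.0003116; adjusted p = 0.7129 with an estimated correlation). Cox7a1 was at log2 -1.72, Ndufs1 at -1.03 and Uqcrc1 at -0.81. The median of this list was -0.46 with TMM, -0.24 with library totals and -0.05 with TPM. Its call held with each, but with TPM this was relative to a median of 0.28 over all genes and does not show a fall of the list. Of 26 fatty acid oxidation genes 4 fell, Hadh among them (log2 -0.76), or 1 when adjusted over the list alone. This list was not called (adjusted p = 0.2086) but was without control mouse 1 (adjusted p = 0.0296), and its median was above 0 with TPM. Of 17 glycolysis and glycogen genes, 8 fell and 3 rose, as also adjusted over the list alone, and the list was not called (adjusted p = 0.06871; without CT-26 mouse 2, adjusted p = 0.001535). Pgam2, a phosphoglycerate mutase of muscle, fell by 1.56 on the log2 scale. Polyamine genes changed in both directions: of 11, 7 fell and 3 rose, as also adjusted over the list alone (adjusted p = 0.02053; adjusted p = 0.3355 with an estimated correlation). Amd1, whose enzyme provides the aminopropyl donor of polyamine synthesis, was 15.6-fold lower (1297 ± 252 to 83.3 ± 30.0 CPM; SD, n = 3), its near-identical copy Amd2 was 14.3-fold lower, and Paox of polyamine breakdown rose 3.02-fold. The median of the polyamine list was -0.58 with TMM, -0.39 with library totals and -0.14 with TPM. Its call held with each, with TPM relative to a median of 0.28 over all genes. Of 17 cholesterol synthesis genes, 9 fell and 3 rose, as also adjusted over the list alone (adjusted p = 0.04578; adjusted p = 0.2675 with an estimated correlation), with Dhcr7 4.01-fold and Hmgcs1 1.99-fold lower and Fdft1 2.68-fold higher. The median of the cholesterol list was -0.67 with TMM, -0.47 with library totals and -0.13 with TPM. Its call was lost with library totals and with TPM, and also without CT-26 mouse 2 (adjusted p = 0.08171), CT-26 mouse 3 (adjusted p = 0.0987) or control mouse 1 (adjusted p = 0.08199).

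Extracellular matrix genes were lower in CT-26 muscle. Of 22, 17 fell, and Lox, whose enzyme cross-links collagen, rose (2 rose and 17 fell when adjusted over the list alone; adjusted p = 3.726e-13; adjusted p = 0.2115 with an estimated correlation). Col1a1 was 16.9-fold lower (372.8 ± 135 to 22.0 ± 9.91 CPM; SD, n = 3), and Col6a2, Col5a1 and Col6a1 were 5.96-fold, 5.51-fold and 5.22-fold lower. Markers of 3 other cell types of muscle were also lower in these libraries, with the same counts adjusted over the list alone except where given. Of 8 fibroblast and fibro-adipogenic progenitor markers 5 fell (adjusted p = 0.008057; adjusted p = 0.4506 with an estimated correlation), among them Clec3b, Pi16 and Dpt, which were 3.99-fold, 2.95-fold and 2.92-fold lower. Pdgfra did not pass (log2 -0.02). Of 7 adipocyte markers 6 fell, or 7 when adjusted over the list alone (adjusted p = 1.23e-10; adjusted p = 0.1143 with an estimated correlation). The lipid droplet gene Plin1 was 9.10-fold, the adipokine genes Cfd and Adipoq 5.18-fold and 5.09-fold lower. Of 8 Schwann cell markers 7 fell (adjusted p = 0.0002309; adjusted p = 0.3323 with an estimated correlation), with the myelin genes Mbp and Pmp22 both at log2 -1.05.

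Blood cell transcripts were higher. Of 13 listed neutrophil markers 8 were measured. A gene near 0 in controls, such as Ngp, could pass the minimum count only through the CT-26 libraries. This favours rises among the measured genes and in their set test. All 8 rose, as also adjusted over the list alone (adjusted p = 6.883e-06, or adjusted p = 0.3355 with an estimated correlation). Their median log2 was 6.44, or 5.07 without CT-26 mouse 1. The median was 2.77 with TPM, where 0.5 is added to every value and the change of low genes is understated. S100a8 rose from 0.0961 ± 0.0540 to 22.2 ± 24.0 CPM (SD, n = 3), and its log2 change was 7.80, or 6.37 without CT-26 mouse 1; S100a9 (7.27, or 5.99) and the receptor Csf3r (3.91, or 3.09) did likewise. Ngp had 2 counts over the 3 control libraries and 1168 over the CT-26 libraries, a ratio of 454.1 (95% counting interval 125.4 to 3754). Its fitted log2 change was 8.33, or 6.25 without CT-26 mouse 1. All 5 erythroid markers rose, as also adjusted over the list alone (adjusted p = 0.0004557; adjusted p = 0.3323 with an estimated correlation), with Alas2 at log2 1.63, Hbb-bs at 1.55 and Hba-a2 at 1.27. Haemoglobin transcripts held 0.0829 to 0.0901% of counts with CT-26 and 0.0195 to 0.0378% in controls. Of 11 macrophage markers Lyz2 and Itgam rose (0 when adjusted over the list alone), the call of Itgam being lost without CT-26 mouse 1 (log2 1.02, adjusted p = 0.07309) or any control (adjusted p = 0.06102 to 0.08044). The macrophage list was not called (adjusted p = 0.4743), but was without CT-26 mouse 2 (adjusted p = 0.001137). Ighm, the only gene of the lymphocyte list measured, fell by 5.52 on the log2 scale (50.7 ± 5.27 to 1.09 ± 0.240 CPM; SD, n = 3). The light chain gene Igkc was at 0.146 to 0.696 CPM in all 6 gastrocnemius libraries, so these Ighm counts cannot be assigned to lymphocytes. Of 10 endothelial markers 2 rose and 2 fell (Kdr log2 -1.69; adjusted p = 0.9753). Of 8 satellite cell markers 1 rose and 4 fell (Cdh15 log2 1.86; adjusted p = 0.6376), and of 7 cell division genes only Aurka fell (log2 -1.82; adjusted p = 0.2077). These counts were the same adjusted over the list alone.

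The gastrocnemius genes with the most extreme changes under the naming rule were Ngp, S100a8, S100a9 and the B-cell chemoattractant gene Cxcl13 among the higher, and Chad, Cilp2, Rmi2 and Mdga1 among the lower. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) rose from 0.228 ± 0.169 to 32.2 ± 28.9 CPM (SD, n = 3; log2 7.12 ± 1.13 SE, adjusted p = 0.002258; 6.23 without CT-26 mouse 1). Chad, a cartilage and tendon matrix gene (ENSMUSG00000039084, chromosome 11, 94565047 to 94569127, overlapping Acsf2), fell from 17.2 ± 8.05 to 0.0657 ± 0.0800 CPM (SD, n = 3; log2 -8.15 ± 0.67 SE, adjusted p = 0.0002275; -9.25 without CT-26 mouse 2). The log2 changes of the other 3 were -6.55 for Cilp2 of cartilage (-7.21 without CT-26 mouse 1), -6.27 for Rmi2 and -6.16 for Mdga1 (-7.16 without CT-26 mouse 1). Trim63 (ENSMUSG00000028834) lies on chromosome 4 at 134315120 to 134329629 and Fbxo32 (ENSMUSG00000022358) on chromosome 15 at 58175879 to 58214932.

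**Figure D2:**
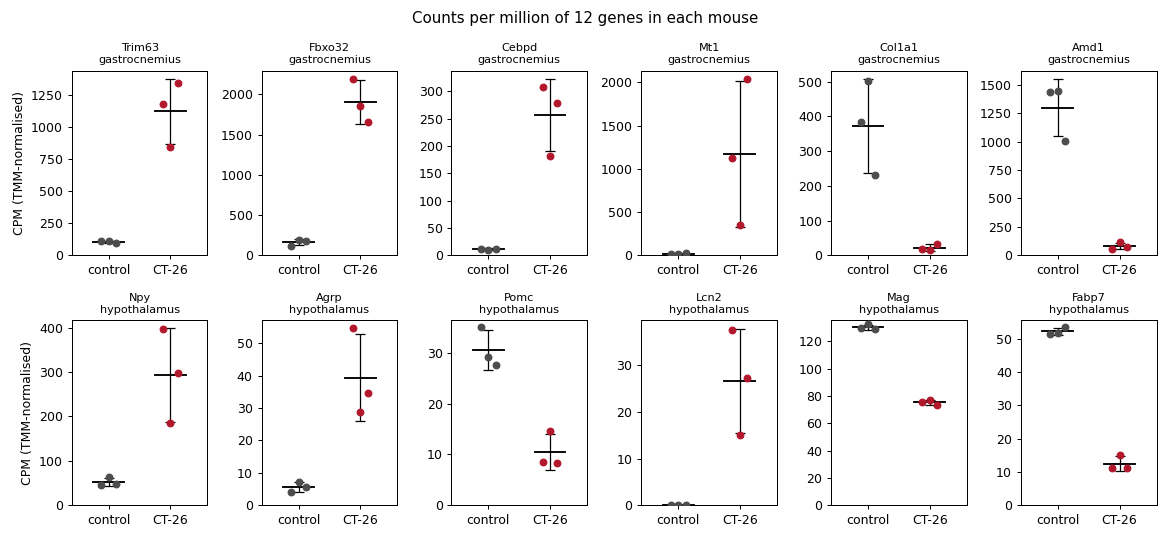
TMM-normalised CPM of 12 genes in each mouse, 6 genes in the gastrocnemius and 6 in the hypothalamus; points are the 3 mice of a group, horizontal bars the mean and error bars the SD, and each panel has its own axis from 0. In none of the 12 panels do the CT-26 and control mice overlap; Trim63 averages 1126 CPM against 105.7 and Agrp 39.4 against 5.53.

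In the CT-26 hypothalamus, the appetite-promoting neuropeptide genes Agrp and Npy were higher and Pomc and Cartpt, whose peptides reduce feeding, were lower. Agrp rose 7.07-fold (5.53 ± 1.51 to 39.4 ± 13.5 CPM; SD, n = 3) and Npy 5.57-fold (52.4 ± 9.35 to 292.7 ± 106 CPM; SD, n = 3), while Pomc was 2.97-fold lower (30.6 ± 3.91 to 10.4 ± 3.58 CPM; SD, n = 3). Among listed genes, 10 of 16 acute phase and 9 of 15 glucocorticoid-responsive genes rose, and 15 of 17 cholesterol synthesis, 8 of 10 oligodendrocyte and 6 of 13 immediate early genes fell. None of these 5 lists passed with a correlation between genes estimated from the libraries (adjusted p = 0.07906, 0.1464, 0.1094, 0.07906 and 0.3269 with an estimated correlation). Of 17961 genes tested, 1575 were called, 708 higher and 867 lower, of which 171 and 61 changed at least 2-fold; 30.3% of genes did not overlap between groups, against 10% by chance. Calls were 45.0% higher with TMM and 57.7% with library totals. The number of calls varied with single libraries: without control mouse 2, 283 were higher and 293 lower; without CT-26 mouse 1, 314 and 397; without CT-26 mouse 3, 439 and 362; and without CT-26 mouse 2, 543 and 498. In 1 fit of all 12 libraries, where the spread, the scaling and the set of genes are shared with the muscle, 108 genes were higher and 54 lower.

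Of 11 orexigenic neuropeptides and receptors, 3 rose and none fell, as also adjusted over the list alone (adjusted p = 0.0007852; adjusted p = 0.1054 with an estimated correlation). These were Agrp (log2 2.82 ± 0.24 SE, adjusted p = 0.0002398), Npy (2.48 ± 0.23 SE, adjusted p = 0.0003386) and the ghrelin receptor gene Ghsr (0.90 ± 0.13 SE, adjusted p = 0.003171). The list mean was 0.46 but its median 0.01, which fell below 0 without CT-26 mouse 1 or control mouse 2. Hcrt (-0.74), Pmch (-0.04) and Gal (0.03) did not pass the test. Agrp (ENSMUSG00000005705, chromosome 8, 105566698 to 105637393) is annotated across Ctcf and Ripor1 on the opposite strand, whose log2 changes were -0.09 and -0.28. Npy (ENSMUSG00000029819) lies on chromosome 6 at 49822710 to 49829507. Of 14 anorexigenic neuropeptides and receptors, Pomc (log2 -1.57 ± 0.19 SE, adjusted p = 0.001019) and Cartpt (-0.67 ± 0.06 SE, adjusted p = 0.0002398) fell and the incretin receptor gene Glp1r rose (0.53), as also adjusted over the list alone. The list was not called (adjusted p = 0.349; without control mouse 2, adjusted p = 0.0475). Crh (0.77 ± 0.35 SE, adjusted p = 0.2076), Trh (0.11 ± 0.11 SE, adjusted p = 0.596; without control mouse 1, 0.27 and adjusted p = 0.04523) and Lepr (0.45) did not pass. Among 15 neuroendocrine peptides 2 rose and 2 fell, as also adjusted over the list alone (adjusted p = 0.9526): the vasopressin gene Avp rose 2.27-fold (354.4 ± 83.2 to 803.7 ± 14.1 CPM; SD, n = 3) and Ghrh of growth hormone release fell by 1.03 on the log2 scale. The median of this list (-0.06) and its camera direction had opposite signs. Of 11 monoamine genes only Th fell (-0.54), also adjusted over the list alone (list adjusted p = 0.6402), a call that was lost without CT-26 mouse 3 (adjusted p = 0.08287) or control mouse 2 (adjusted p = 0.07437).

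Several inflammation and hormone response genes rose. Of 16 IL-6/STAT3 and acute phase genes, 10 rose and none fell, or 11 and 1 when adjusted over the list alone (adjusted p = 7.697e-22; adjusted p = 0.07906 with an estimated correlation). Lcn2, an iron-siderophore-binding protein gene (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 0.0786 ± 0.0266 to 26.6 ± 11.2 CPM (SD, n = 3; log2 8.36 ± 0.51 SE, adjusted p = 1.813e-05). The metalloreductase gene Steap4 rose 10.4-fold and the interleukin 1 receptor gene Il1r1 3.18-fold, while Socs3 did not pass (0.45 ± 0.20 SE, adjusted p = 0.1929). Saa3, with 2 counts in the controls and 239 with CT-26, had a ratio of 100.4 (95% counting interval 27.5 to 834.1). Of 11 NF-kB targets 4 rose and 1 fell, or 7 and 1 when adjusted over the list alone (adjusted p = 0.0001684; adjusted p = 0.1094 with an estimated correlation). Icam1 was at log2 1.78, Il1b at 2.56 and Vcam1 at -0.39. Neutrophil transcripts rose in the same libraries, and Lcn2 is also a neutrophil granule gene. Of 15 glucocorticoid-responsive genes 9 rose, or 12 when adjusted over the list alone (adjusted p = 5.308e-13; adjusted p = 0.1464 with an estimated correlation). Cebpd rose 2.75-fold, Zbtb16 2.32-fold and Fkbp5 2.24-fold. Of 22 interferon response genes Ifit3 and Ifitm3 rose and Irf9 fell (-0.58), or 3 and 2 when adjusted over the list alone (list adjusted p = 0.6201). Of 16 ATF4 stress genes Atf3 fell (-1.31), or 1 rose and 3 fell when adjusted over the list alone (list adjusted p = 0.7121). Calls of 3 genes were lost without single libraries: Vcam1 (adjusted p up to 0.07437 without control mouse 2), Irf9 (up to 0.06478, the same mouse) and Atf3 (up to 0.1003, the same mouse).

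Part of the listed metabolic, myelin and activity genes fell. Of 17 cholesterol synthesis genes 15 fell, or 16 when adjusted over the list alone (adjusted p = 3.667e-26; adjusted p = 0.1094 with an estimated correlation), by small amounts: Hmgcs1 was at log2 -0.58, Sc5d at -0.51 and Fdft1 at -0.39. Of 10 oligodendrocyte markers 8 fell, or 9 when adjusted over the list alone (adjusted p = 1.309e-22; adjusted p = 0.07906 with an estimated correlation). The myelin genes Mag and Mbp were 1.73-fold and 1.55-fold lower, Mag going from 130.3 ± 1.93 to 75.4 ± 1.88 CPM (SD, n = 3), whereas Mal (log2 -0.09) and Mobp (-0.22) did not pass. Of 8 oligodendrocyte precursor markers 4 fell, or 5 when adjusted over the list alone (adjusted p = 3.87e-10; adjusted p = 0.07906 with an estimated correlation). The 3 named ones, Enpp6 (-1.65), Bcas1 (-0.98) and Gpr17 (-0.86), mark differentiating cells, and the progenitor markers Pdgfra (0.01) and Cspg4 (0.10) did not pass. Of 13 immediate early genes, which follow neuronal activity, 6 fell, or 9 when adjusted over the list alone (adjusted p = 7.85e-08; adjusted p = 0.3269 with an estimated correlation). Fosb was at -1.83, Egr4 at -1.54 and Fosl2 at -0.93, and Fos did not pass (-1.10). Control mouse 2 was highest in these 4 genes, with Fosb at 31.5 CPM against 17.3 and 14.0 CPM in the other controls. Without it Fosb was at -1.40, Egr4 at -1.10, Fosl2 at -0.75 and Fos at -0.61, so this mouse carried part of the change. Control mouse 2 also stood apart in some transcripts: the dopamine transporter gene Slc6a3 was at 28.9 CPM there and at 2.43 to 3.64 CPM in the other 5 libraries. Of 14 endoplasmic reticulum chaperone genes 5 fell, or 8 when adjusted over the list alone (adjusted p = 5.8e-05; adjusted p = 0.4157 with an estimated correlation). Creld2 was at -0.46, Pdia4 at -0.39 and Calr at -0.31. Each of these 3 calls was lost without control mouse 2 and without others (adjusted p up to 0.09677, 0.1024 and 0.08803). Of 13 mitochondrially encoded transcripts mt-Atp6 (-0.62) and mt-Nd2 (-0.32) fell, as also adjusted over the list alone (adjusted p = 0.01568; adjusted p = 0.5553 with an estimated correlation). Both calls were lost without CT-26 mouse 1 (adjusted p = 0.06483 and 0.09154), and that of the list without CT-26 mouse 2 (adjusted p = 0.1207) or control mouse 1 (adjusted p = 0.2034). The list call was also lost with TPM.

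**Figure D3:**
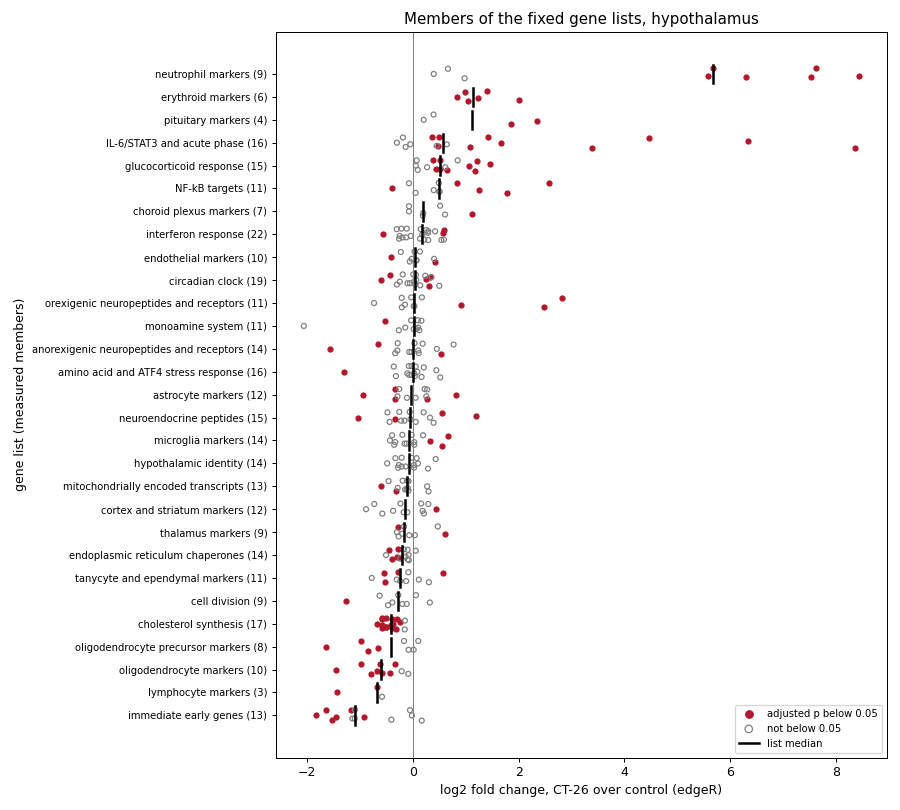
Log2 fold change (CT-26 over control) of each measured member of the fixed gene lists in the hypothalamus, 1 line per list with its number of measured members; filled points have an adjusted p below 0.05, open points do not, and black bars are list medians. Most lists have medians within 1 log2 unit of 0; the median of the 9 neutrophil genes (5.68) lies farthest to the right and that of the 13 immediate early genes (-1.10) farthest to the left.

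Blood cell markers were higher in the hypothalamus too. Of 13 listed neutrophil markers 9 were measured. Cxcr2, with 0 control counts, could pass the minimum count only through the CT-26 libraries, which favours rises here too. Of the 9, 6 rose, or 7 when adjusted over the list alone (adjusted p = 1.776e-12, or adjusted p = 0.1738 with an estimated correlation). The median log2 was 5.68, or 5.58 with Cxcr2 at its bound. It was 4.60 or 6.27 without CT-26 mouse 1 or control mouse 3. With TPM and its added 0.5 the median was 1.53. S100a8 changed by 7.62 (6.22 without CT-26 mouse 1, 6.99 and 9.47 without control mouse 2 and 3), S100a9 by 6.30 (5.09 without CT-26 mouse 1) and Ngp by 5.58 (4.22 without CT-26 mouse 1 and 6.41 without control mouse 3). The call of Ngp was lost without control mouse 2 (5.17, adjusted p = 0.06676). Cxcr2 had 0 counts over the 3 controls and 131 with CT-26, at least 36.7-fold higher against a floor of 3 counts over the control group. All 6 erythroid markers rose, as also adjusted over the list alone (adjusted p = 5.263e-16; adjusted p = 0.1054 with an estimated correlation), with Alas2 at 1.39, Hba-a1 at 1.23 and Hbb-bs at 1.04. Haemoglobin transcripts held 0.0552 to 0.0708% of counts with CT-26 and 0.0237 to 0.0373% in controls. Of 12 listed lymphocyte markers 3 were measured. Trac (-1.43, from 2.80 to 1.03 CPM) and Ighm (-0.68) fell, as also adjusted over the list alone, and no set test was run. In the gastrocnemius Ighm counts could not be assigned to lymphocytes. With so few markers measured, a change in lymphocytes cannot be read from this list.

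Other brain cell and region lists were not called. Of 14 microglia markers only the complement genes C1qa, C1qb and C1qc rose, as also adjusted over the list alone (C1qc log2 0.66; list adjusted p = 0.6396, with a median of -0.08 opposite to the test's direction). Of 12 astrocyte markers 2 rose and 3 fell, or 4 and 5 when adjusted over the list alone (adjusted p = 0.6201), with the water channel gene Aqp4 1.93-fold lower. Of 10 endothelial markers 1 rose and Kdr fell (-0.41), or 2 and 1 when adjusted over the list alone (adjusted p = 0.6396). Of 11 tanycyte and ependymal markers 1 rose and 3 fell, Foxj1 at -0.54, as also adjusted over the list alone. The tanycyte list (adjusted p = 0.1988) was called without CT-26 mouse 2 (adjusted p = 0.03306), control mouse 2 (adjusted p = 0.04034) or control mouse 3 (adjusted p = 0.0458). For the next lists, counts were the same adjusted over the list alone unless given. Of 19 clock genes 3 rose and 2 fell (6 and 5 adjusted over the list alone), with Tef at 0.31 (list adjusted p = 0.6021). Fry's mixed test of the clock list gave an adjusted p of 0.0009677. Of 9 cell division genes Top2a fell (-1.27; list adjusted p = 0.1988), and of 7 choroid plexus markers Aqp1 rose (1.11; list adjusted p = 0.1407). None of 14 hypothalamic identity genes was called by edgeR (list adjusted p = 0.6021). Of 9 thalamus markers 1 rose, Prkcd at 0.61, and 1 fell (1 and 2 adjusted over the list alone; list adjusted p = 0.6021), and of 12 cortex and striatum markers 1 rose, Ppp1r1b at 0.43 (list adjusted p = 0.929). Of 4 pituitary markers Cga (2.35) and Pitx1 (1.86) rose, or 3 adjusted over the list alone, with no set test. The calls of Kdr (without control mouse 2, adjusted p = 0.1116), Top2a (without the same mouse, 0.0994), Aqp1 (without the same mouse, 0.1192) and Ppp1r1b (without CT-26 mouse 1, 0.09548) were lost without these and other single libraries.

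Under the naming rule the most extreme hypothalamus genes were Lcn2, S100a8, S100a9 and Ngp among the higher, and Hspa1b, Klk6, Hspa1a and Fabp7 among the lower. Fabp7, a fatty acid binding protein gene of glial progenitors (ENSMUSG00000019874, chromosome 10, 57784881 to 57788450), fell from 52.2 ± 1.05 to 12.5 ± 2.34 CPM (SD, n = 3; log2 -2.07 ± 0.11 SE, adjusted p = 9.374e-06). Klk6, a serine protease gene of oligodendrocytes (ENSMUSG00000050063, chromosome 7, 43824499 to 43832030), fell from 4.83 ± 1.29 to 0.742 ± 0.263 CPM (SD, n = 3; log2 -2.75 ± 0.27 SE, adjusted p = 0.0004775). The near-identical heat shock genes Hspa1b (log2 -3.12) and Hspa1a (-2.23) were set by control mouse 2, at 105.8 and 128.4 CPM. Without it they were at -1.49 (adjusted p = 0.003345) and -0.77 (adjusted p = 0.009689), and both calls were lost without any 1 of the CT-26 mice (adjusted p = 0.05172 to 0.09389 and 0.08749 to 0.1477).

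The interaction term was called for 4952 of 18746 genes, 2323 with a higher and 2629 with a lower log2 change in the gastrocnemius. Of these, 4510 were among the 13572 genes tested in both tissues, and only for those is the CT-26 effect described as differing. Atrophy and metallothionein genes were among those with a higher change in the muscle: Fbxo32 rose by 3.54 there and fell by 0.50 in the hypothalamus, a difference of 4.02 ± 0.26 SE (adjusted p = 1.626e-06), and Mt2 rose by 6.36 and 0.51, a difference of 5.84 ± 0.58 SE (adjusted p = 3.25e-05; 5.15 without CT-26 mouse 3). Calls were 46.9% higher with TMM, 66.5% with library totals and 82.5% with TPM. Without control mouse 1 there were 1527 higher and 1696 lower, and without control mouse 2 1492 and 1712.

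Among called genes under the naming rule, the other largest positive differences were Mt1 (5.18, or 4.50 without CT-26 mouse 3), the acyltransferase gene Oacyl (5.08) and the GABA-B receptor subunit gene Gabbr2 (4.34, or 3.65 without CT-26 mouse 1). Oacyl had 3 counts over the control gastrocnemius libraries and 229 with CT-26, a ratio of 59.4 (95% counting interval 20.05 to 289.9). The largest negative ones were Chad (-8.93, or -9.70 without CT-26 mouse 2), the cytochrome P450 gene Cyp2f2 (-6.78, or -7.52 without control mouse 1), Cilp2 (-6.33, between -5.72 and -7.04 without single CT-26 mice) and Mdga1 (-5.87, or -6.90 without CT-26 mouse 1). Chad and Cilp2 were near the floor in the hypothalamus, with 63 and 36 counts over the CT-26 and 33 and 36 over the control libraries. Their differences mainly restate the fall in the muscle. Cyp2f2 fell by 3.83 in the gastrocnemius and rose by 2.92 in the hypothalamus, where CT-26 mouse 2 was at 6.78 CPM. Of the fixed genes, Cebpd (3.04 ± 0.27 SE, adjusted p = 1.85e-05), Socs3 (2.23 ± 0.43 SE, adjusted p = 0.002296) and Foxo1 (1.66 ± 0.30 SE, adjusted p = 0.001314) had a higher change in the muscle. The differences of Pdk4 (0.67 ± 0.41 SE, adjusted p = 0.2503), Lcn2 (-1.58 ± 1.52 SE, adjusted p = 0.4934) and Myh4 (-1.32 ± 0.64 SE, adjusted p = 0.1513) did not pass. That of Myh4 passed without CT-26 mouse 2 (-2.34, adjusted p = 0.001863). In the hypothalamus Myh4 averaged only 9.48 CPM with CT-26 and 6.93 CPM in controls, a trace of its muscle level. Its difference therefore rests mainly on the muscle.

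Calls in the same direction were shared more often than expected from their numbers among the 13572 genes. Higher in both tissues were 256 genes, against 115.3 expected for independent lists (two-sided Fisher's exact test, p = 6.96e-42), and lower in both were 243, against 130.2 expected (p = 2.97e-25). These counts depended on the scaling: genes higher in both tissues and genes lower in both tissues were 378 and 129 with library totals only and 116 and 45 with limma on log2 TPM. Genes higher in the gastrocnemius and lower in the hypothalamus numbered 73 against 142.3 expected, and those with the opposite directions 53 against 105.5. Shared higher genes included Lcn2, S100a8, Cebpd and Fkbp5, and shared lower genes included Mbp and Hmgcs1. Across these genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.299 and a Spearman rho of 0.203. Per the titles both tissues came from the same 6 mice, so chance differences between the mice, and blood in both tissues, enter both comparisons.

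**Figure D4:**
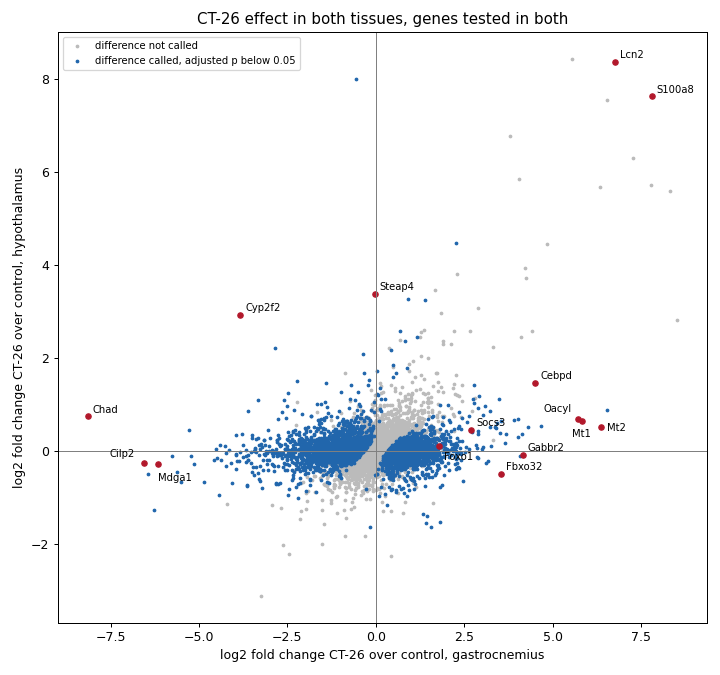
Log2 fold change (CT-26 over control) in the gastrocnemius (horizontal axis) and the hypothalamus (vertical axis) of the 13572 genes tested in both; blue points have a called difference between tissues, grey points do not, and named genes are in red. Lcn2 and S100a8 lie high on both axes, while Fbxo32 and Mt2 lie far right near the horizontal line and Chad far left.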

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

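The interaction test, the splits of the mice into other groups, the scalings and the fits without single libraries were planned. The neutrophil to erythroid ratios, the comparison between tissues of a mouse, Cochran's Q, the region medians and the tendon genes were chosen after the results were seen. So was the use of the scalings and of the fit without control library 2 as tests of an explanation. Of the 108 named genes reported here and tested in both tissues, 76 had a CT-26 effect that differed between the gastrocnemius and the hypothalamus by the interaction test, 37 with a higher and 39 with a lower log2 change in the gastrocnemius. Of these, 5 genes (Calr, Fdft1, Prkcd, Fbxo32 and Cyp2f2) were called in opposite directions in the 2 tissues. The hypothalamus call of Calr was lost without any of 3 single libraries (adjusted p up to 0.08803). Fdft1 overlaps the lysosomal gene Ctsb, which had 3.97 times its counts, so reads of the 2 genes cannot be told apart with certainty. Many named genes were chosen for a change in 1 tissue, which favours differences between tissues. Chad, Cilp2, Myl1 and Casq1 were not called in the hypothalamus, where Chad had 63 and 33 counts with CT-26 and control and Cilp2 36 and 36. Their differences rest mainly on the muscle. Among neutrophil genes Csf3r differed, with a hypothalamus change of 0.66 that was not called. The differences of S100a8 (0.22), S100a9 (0.99), Ngp (2.83) and Cxcr2 (-2.36) did not pass. The differences in log2 change, gastrocnemius minus hypothalamus, were for the higher genes Mt2 5.84, Mt1 5.18, Oacyl 5.08, Gabbr2 4.34, Fbxo32 4.02, Serpina3n 3.32, Csf3r 3.24, Cebpd 3.04, Il6ra 2.90, Eif4ebp1 2.84, Cdh15 2.64, Cdkn1a 2.38, Socs3 2.23. Smaller ones were Akt1 2.19, Chac1 2.12, Ctsl 1.88, Itgam 1.86, Gadd45a 1.83, Fdft1 1.79, Psmd4 1.76, Fkbp5 1.75, Foxo1 1.66, Fbxo31 1.55, Bnip3 1.49, Enpp6 1.44, Xbp1 1.44. The remaining higher genes were Psma7 1.43, Psmd2 1.35, Paox 1.35, Bnip3l 1.22, Runx1 1.04, Chrnb1 1.03, Nfkbiz 0.98, Calr 0.92, Dnajb9 0.76, Slc3a2 0.72, Dnajc3 0.70. For the lower genes they were Chad -8.93, Cyp2f2 -6.78, Cilp2 -6.33, Mdga1 -5.87, Rmi2 -5.07, Ighm -4.85, Amd1 -3.88, Amd2 -3.85, Myl1 -3.50, Pvalb -3.48, Casq1 -3.47, Steap4 -3.42, Plin1 -2.80. Nearer to 0 were Col6a1 -2.65, Col6a2 -2.62, Col5a1 -2.49, Cfd -2.31, Pgam2 -1.86, Adipoq -1.78, Pi16 -1.77, Clec3b -1.64, Aqp4 -1.57, Dhcr7 -1.50, Mag -1.49, Prkcd -1.49, Kdr -1.30. The remaining lower genes were mt-Co2 -1.26, mt-Nd4l -1.21, Ndufs1 -1.15, Il1r1 -1.10, Aqp1 -0.97, Uqcrc1 -0.93, mt-Nd5 -0.92, Icam1 -0.91, Hadh -0.72, Tef -0.55, Sc5d -0.54, Pmp22 -0.51, Hmgcs1 -0.42.

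Between CT-26 and control, 5417 genes were called in the gastrocnemius, and the highest of the other splits of the 6 mice gave 0 by the same edgeR test. In the hypothalamus the values were 1575 and 1, and for the difference between tissues 4952 and 1. In each case only the real split, 1 of 10, gave as many, and 10 splits cannot give a share under 0.05. Every other split mixed CT-26 and control mice. Any large difference between the groups, whatever its source, would then widen the spread within the mixed groups and lower their calls. The counts above therefore do not tell a CT-26 effect from another difference between the groups.

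Neutrophil transcripts were higher in both tissues of CT-26 mice, and so were erythroid transcripts. More residual blood of unchanged composition would leave the neutrophil to erythroid ratio as it was. That ratio rose by 5.325 on the log2 scale (SE 0.923) in the gastrocnemius and by 5.106 (SE 1.22) in the hypothalamus for S100a8, S100a9, Ngp, Retnlg, Cxcr2 and Mmp8, 6 genes with a low background that were picked after the result of the whole list was seen; with all listed genes the changes were 3.931 (SE 0.836) and 1.28 (SE 0.794). The last value lay within 2 SE of 0 with overlapping groups, so in the hypothalamus the argument against such blood rests on the 6 picked genes. These 6 were picked for control means under 1 CPM in both tissues, which itself favours a rise. In the CT-26 mice, paired by the numbers in the titles, the ratio differed by 0.3676 on the log2 scale between the 2 tissues of a mouse and by 1.965 between mice (0.4386 and 0.7422 without mouse 1, which carried most of the second value), with 16.2, 3.00 and 2.43% of erythroid CPM in the gastrocnemius and 13.8, 3.51 and 1.55% in the hypothalamus, so blood richer in neutrophils left in both tissues may explain part of the pattern. Neutrophils within the tissues and a changed expression per neutrophil were not tested and stay open.

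Oligodendrocyte transcripts were lower in the CT-26 hypothalamus. The listed genes changed by different amounts (chi-square test of Cochran's Q over 10 genes and their standard errors, Q 140.5, p = 8.17e-26). A lower share of oligodendrocytes would lower them alike only if no other cells expressed them. This test therefore cannot decide whether that share was lower. Control library 2, with its dopamine neuron and heat shock transcripts, was not the cause, since 8 of the 10 genes fell without it. A shifted dissection cannot be told apart from a change in the cells. The median log2 change was -0.08388 (-0.2714 to 0.0552) for hypothalamic identity genes and -0.6089 for the oligodendrocyte list. It was -0.1706 (-0.2937 to 0.4678) for thalamus and -0.1443 (-0.4801 to 0.1925) for cortex and striatum markers. The ranges are 95% bootstrap intervals from 10000 resamplings of the listed genes and do not cover the spread between mice. The median of the 4 measured pituitary markers was 1.1238, with all 4 above 0. White matter at the edge of the tissue has no list here. A biological effect of CT-26 on oligodendrocytes stays open, as untested.

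Extracellular matrix transcripts were lower in the CT-26 gastrocnemius. Scaling was not the cause, since the list's median was -1.0467 or lower with each scaling. The fibroblast markers changed by different amounts (chi-square test of Cochran's Q over the listed genes and their standard errors, Q 93.97, p = 1.89e-17). A lower share of fibroblasts would lower them alike only if no other cells expressed them. Cochran's Q therefore cannot decide whether that share was lower. Less tendon in the sampled piece cannot be told apart from a change in the muscle: 7 of 8 tendon genes fell, among them Kera (log2 -5.76), Tnmd (-5.14) and Comp (-5.01), while Scx rose (1.08), and some of these genes had been noticed in these data first. A biological effect of CT-26 on the matrix stays open, as untested.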

How the results depend on the processing

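The alternatives were planned before the data were examined; where no construction is named, the cause was not tested. No named gene that was called changed sign under any of them. Among all genes called, the sign turned with TPM for 85 in the gastrocnemius, 4 in the hypothalamus and 219 of the tissue differences, with effective-length offsets for 5, 4 and 5, and without control mouse 1 for 1 tissue difference. The median of the called orexigenic list, 0.01, turned to -0.01 without CT-26 mouse 1 or control mouse 2, and medians of lists that were not called turned under several alternatives. With library totals, 1662 gastrocnemius genes were lower and 1634 genes had a lower effect in the gastrocnemius, and 129 were lower in both tissues. With TPM there were 4473 higher and 1018 lower genes in the gastrocnemius, 245 and 275 in the hypothalamus, 4081 and 868 for the difference between tissues, and 116 and 45 shared. An adjusted p below 0.01, a stricter threshold by construction, gave 1507 and 1344, 196 and 224, 1283 and 1400, and 66 and 52. One fit of all 12 libraries, where both tissues share the estimate of the spread, the scaling and the 18746 genes tested, gave 3984 lower gastrocnemius genes and 108 higher and 54 lower hypothalamus genes. With no low-count filter, the hypothalamus genes higher in CT-26 were 1307 and the genes higher in both tissues 437; with effective-length offsets, 569 hypothalamus genes were lower and 163 and 149 genes were shared. DESeq2 called 95.8% of the gastrocnemius calls, 89.5% of the hypothalamus calls and 98.4% of the tissue differences, RLE factors 99.3, 97.6 and 97.8%, and TPM 69.2, 30.6 and 58.3%. Of the calls of named genes, 27 were lost in the fit of all 12 libraries, 21 with TPM, 20 at an adjusted p below 0.01, 3 with effective-length offsets, 3 with a block and 2 with DESeq2; 2 were added with no low-count filter and 1 each with TPM and a block. The test fry ended 7 list calls: endoplasmic reticulum chaperones (adjusted p = 0.07614) and nuclear-encoded oxidative phosphorylation (0.1475) in the gastrocnemius, and glucocorticoid response (0.05209), endoplasmic reticulum chaperones (0.1181), mitochondrially encoded transcripts (0.2133), immediate early genes (0.1595) and neutrophil markers (0.09453) in the hypothalamus. It called the cell division list of the gastrocnemius (0.01438), which camera did not. Of the list calls, 6 were lost at an adjusted p below 0.01: amino acid stress, endoplasmic reticulum chaperones, denervation, polyamine and cholesterol in the gastrocnemius and mitochondrially encoded transcripts in the hypothalamus. The gastrocnemius cholesterol call was also lost with DESeq2, library totals, TPM and a block, the denervation call with TPM and CPM of 1 in 3 libraries, and the hypothalamus mitochondrial call with TPM, effective-length offsets and 1 fit of all 12 libraries. Up to 3 were lost without a single mouse number of 1 group. Lists were added too: up to 4 in that way, 3 with no low-count filter, 2 each with effective-length offsets and a block, and 1 each with DESeq2, library totals, TPM and 1 fit of all 12 libraries.

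Leaving out each library or mouse in turn, which also lowers the number of mice, gave 1768 to 2779 higher and 1779 to 2671 lower genes in the gastrocnemius, 283 to 543 and 293 to 725 in the hypothalamus, and 1492 to 2387 and 1696 to 2349 for the difference between tissues. The lowest counts came without control mouse 1 in the gastrocnemius (3547 calls) and without control mouse 2 in the hypothalamus (576) and for the difference (3204). Of the named genes, 3 lost their call in this way in the gastrocnemius (adjusted p = 0.05114 to 0.08044) and 16 in the hypothalamus (adjusted p = 0.05172 to 0.1477). With the mouse as a block, 3867 tissue differences were called (1792 higher, 2075 lower). Blocking on the mouse number within a tissue, where CT-26 and control mice share only that number, gave 5721 calls in the gastrocnemius and 1111 in the hypothalamus. With 3 mice per group, genes near the minimum count and small changes were the least well measured.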

Other observations

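The genes in this part were chosen after their values were seen, and all p-values are adjusted over all genes of the tissue. In the CT-26 gastrocnemius the stretch-responsive gene Ankrd1 rose from 5.90 ± 1.31 to 117.5 ± 44.6 CPM (SD, n = 3; adjusted p = 0.0001649), the calcium pump regulator gene Sln rose by 3.45 on the log2 scale (adjusted p = 0.001423) and the p53 target Sesn1 by 3.66 (adjusted p = 0.0004457). The myokine gene Ostn fell from 40.6 ± 4.23 to 2.27 ± 0.561 CPM (SD, n = 3; adjusted p = 5.07e-05), and Igfbp5 from 792.1 ± 175 to 33.1 ± 17.0 CPM (SD, n = 3; adjusted p = 0.000277). The creatine synthesis gene Gamt fell by 4.86 on the log2 scale (adjusted p = 0.0002251). Among clock genes, Dbp fell by 2.89 (adjusted p = 0.00113) and Arntl rose by 1.32 (adjusted p = 0.0005738).

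In the CT-26 hypothalamus, Vwf of vessel walls rose by 2.58 on the log2 scale (adjusted p = 1.078e-05), the acute phase gene Lrg1 by 4.46 on the log2 scale (adjusted p = 0.0001058) and the complement gene C3 by 1.84 (adjusted p = 0.0009958). The hypoxia-related gene Hif3a rose by 2.29 (adjusted p = 6.132e-05) and the cold-induced gene Rbm3 by 1.16 (adjusted p = 0.000459). The small heat shock protein gene Cryab fell from 84.1 ± 6.10 to 31.9 ± 4.66 CPM (SD, n = 3; adjusted p = 3.702e-05), and the peptide gene Npvf fell by 1.14 on the log2 scale (adjusted p = 0.02102).

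Control mouse 2 had high heat shock transcripts in both tissues. In the gastrocnemius Hspa1a and Hspa1b were at 177.9 and 193.7 CPM there and at 3.33 to 40.8 and 1.90 to 25.6 CPM in the other 5 libraries. In the hypothalamus they were at 128.4 and 105.8 CPM there and at 11.2 to 23.3 and 4.96 to 18.4 CPM in the others.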
